A study of Homo sapiens with 8 samples.

How the data were processed

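Total RNA of cord-blood CD34+ cells with an empty vector or an shRNA vector against Drosha was enriched for small RNA by gel size selection and sequenced on the SOLiD 4.0 platform, per the labels' protocols. The submitters' processing notes name cutadapt 0.9.3, Bowtie 0.12.7 and the hg19 build, without stating their roles; the counting method, the miRBase release and the handling of reads that match several miRNAs are not given in the sources used here. The deposited table holds, in log2 units, the authors' scaled values of 1733 mature miRNAs in 8 libraries, 1 column per library, each of which was matched by name to the label of 1 sample. No other column of sample values was present (0 columns not used).

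A count-based test was not run on the deposited table because its unit is log2. The base and offset of the log were worked out from the values. Taking 2 to the power of each value and subtracting 1 gave whole multiples of 1 unit per library in 100% of the values under 100 reads, allowing for rounding of the deposited values by up to 0.005. The values are therefore log2(scaled reads + 1), with 0.407 to 2.32 scaled units per read depending on the library. Reads recovered in this way ranged from 99464 to 864873 per library, an 8.70-fold range. Scaled sums still differed between libraries, so the authors' scaling was not to the sum of miRNA reads; nor did it equal a median-of-ratios scaling, since median ratios to a common reference ran from 0.647 to 1.52. Its reference is unstated. Scaling to a total that includes other RNA makes a miRNA value depend on how much of that other RNA a library holds, and no scaling of this kind can show a change in miRNA per cell.

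The labels define 4 groups of 2 libraries. Replicates were compared before averaging: chi-square statistics of their reads per degree of freedom were 2.13 (EV, day 0), 38.5 (shDrosha, day 0), 15.6 (EV, day 7) and 25.9 (shDrosha, day 7), over miRNAs with at least 10 reads, so each library was counted separately. The test statistics, comparisons, lists, alternatives and the rule for naming miRNAs were fixed before the data were examined, except for the alternatives and tests named as chosen later. Fixed then were the design without a block for the replicate number and the miRNA filter, which kept the 606 miRNAs above 0 in at least 2 of the 8 libraries.

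limma 3.58.1 (R 4.3.3) fitted means of 4 groups to the deposited log2 values of all 8 libraries, which gave 4 residual degrees of freedom and 1.50 prior degrees of freedom from eBayes with a trend. There were 6 contrasts: day 7 against day 0 in each vector, shDrosha against EV at each day, the difference between the latter pair (interaction) and their mean. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Fold changes are on the log2(scaled reads + 1) scale, with an offset of 1, which understates the change of miRNAs with few reads. Where a whole group was at 0 reads, the text gives a lower bound computed against 3 reads per library in the shallower library of that group. For the interaction and the mean effect, which join 4 groups, no bound was computed, and fitted values with an offset of 10 are given beside those with an offset of 1. Where a group held 1 to 3 reads in all, it gives the ratio of summed scaled reads with an exact 95% binomial interval; such intervals and bounds cover counting error only.

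Lists of miRNAs written beforehand, 16 in number and 15 with at least 3 measured members, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list moves on balance and does not compare it with other miRNAs. They were stem-cell-associated, HOX-cluster, myeloid, monocyte and inflammatory, erythroid, lymphoid, mesenchymal, epithelial, other-tissue, 17-92 and paralogs, 23a/27a/24 clusters, let-7 family, 14q32 cluster, C19MC, Drosha-independent (miR-320, miR-484 and mirtrons) and entries overlapping other small RNAs. With an estimated correlation camera also uses only the 4 residual degrees of freedom, so calls can end without any correlation between miRNAs. For the lymphoid list in EV from day 0 to day 7, the estimated correlation was -0.034, below the preset one. Its unadjusted camera p still rose, from 0.018 to 0.066. All arms of a precursor counted as members, and some miRNAs stand in more than 1 list. The miRNAs named were up to 10 per direction with the largest change past the threshold, a mean level at or above the median and groups without overlap; up to 4 of the most abundant members of a list; 16 miRNAs fixed by name; and up to 5 per direction for the interaction and the mean effect. List members were named only for the lists that the text describes by example. miR-1226, miR-1227, miR-320c, miR-1234 and miR-124 as a single case were described after their values were seen.

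Some miRNAs share reads with near-identical copies. miR-199a-3p and miR-199b-3p had identical values, miR-151-5p and miR-151b nearly so, and members of the miR-320, let-7, miR-17/20/106 and miR-181 families differ by few bases, so values within these families are uncertain. Molecular identifiers are not given in the sources used here, so reads may not be independent molecules.

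The fit was tested on simulated data for shDrosha against EV at day 7, with 200 of 606 miRNAs changed in 20 runs. It recovered 41.9% of 2-fold and 61.9% of 4-fold changes over all miRNAs, and 79.0% and 97.2% of those with at least 40 reads. Unchanged miRNAs made up 5.43% of calls over all depths, 1.87% at 40 reads or more and 21.5% below. Lists of 12 members changed 2-fold passed an unadjusted p of 0.05 in 100% of 50 runs and unchanged ones in 4%. The list runs used a dispersion of 0.0092. Real replicates had chi-square statistics of 2.13 to 38.5 per degree of freedom. Whether the simulated data matched this spread, or the correlation between miRNAs, was not tested. The simulated shares of false calls may therefore be too low for the real libraries, and the recovered shares too high.

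Alternatives were equal library medians, quantile normalization, no filter, detection in all 8 libraries, only miRNAs at or above the median mean level, an offset of 10, eBayes without trend and with robust settings, a block for the replicate number, only the 4 libraries of a contrast, and each library left out in turn. Chosen after seeing the data were scaling to the miRNA read total, a filter of at least 10 reads in 2 libraries, limma's voom on the recovered reads, and the Drosha-independent list without the miR-320 family or, under each scaling at day 7, without the miRNAs at 0 reads in all 4 libraries. Medians of all miRNAs moved with scaling: relative to the deposited values by 0.57, 0.96, 0.25, 0.64, 0.39 and 0.44 on the log2 scale with equal library medians, for the 6 contrasts in the order above. Positions of miRNA genes were taken from GENCODE v29 on GRCh38 by gene name, using Python 3.11.15 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9.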

Results

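Small RNA libraries were compared from CD34+ hematopoietic stem and progenitor cells (HSPCs) of human cord blood, the blood-forming cells from which granulocytes, monocytes, red cells and lymphocytes arise. The cells carried an empty lentivector (EV) or a vector for a short hairpin RNA against Drosha (shDrosha), the nuclear RNase III enzyme that releases precursor miRNAs from their primary transcripts. One set of libraries was made right after sorting (day 0), from cells in serum-free medium with early-acting cytokines. The other was made after 7 days of liquid culture with G-CSF and GM-CSF, which drives myeloid differentiation (day 7). Each of the 4 groups held 2 libraries sequenced on the SOLiD 4.0 platform. The values were log2(scaled reads + 1) for 1733 mature miRNAs, of which 686 were above 0 in some library and 606 in at least 2 libraries.

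Depth differed between groups. The EV libraries of day 0 held 265863 and 262892 miRNA reads, the shDrosha libraries of day 0 held 728079 and 864873, the EV libraries of day 7 held 122329 and 99464, and the shDrosha libraries of day 7 held 125281 and 150408. Drosha mRNA was not measured by these small RNA libraries, so the knockdown itself has no readout here. The control is labelled an empty vector, so an effect of losing Drosha cannot be told apart from another effect of the hairpin vector. Below, a knockdown effect means the difference between the vectors. The labels do not say whether the 2 libraries of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. Below, ± after a log2 fold change is the standard error of the limma fit with 2 libraries per group, and adjusted p-values are Benjamini-Hochberg values from limma over the 606 miRNAs.

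The summed miRNA signal was alike in both vectors at day 0 and lower at day 7, more so with shDrosha. Scaled miRNA reads summed to 355640 ± 5586 (SD, n = 2) in EV and 362030 ± 13851 (SD, n = 2) in shDrosha cells at day 0, a ratio of 1.02. At day 7 the sums were 224540 ± 8674 (SD, n = 2) in EV, 0.631 of the day 0 level, and 149150 ± 3366 (SD, n = 2) in shDrosha, 0.412 of its day 0 level and 0.664 of EV. The 2 libraries of each group lay closer to each other than to any library of the groups at the other day. Over both vectors the 4 libraries of day 7 lay below the 4 of day 0 (exact permutation test, two-sided, p = 0.029, the smallest that 70 splits allow; chosen after seeing the data). That test took the 8 libraries as independent and ignored the vector. The ratios between single groups were not tested, since with 2 libraries against 2 an exact permutation test cannot go below a two-sided p of 0.333. The same limit would hold for the days if the 2 libraries of a group are repeats of 1 sample. Thinned to 99464 reads each, the libraries held 431 and 433 miRNAs (EV, day 0), 408 and 409 (shDrosha, day 0), 412 and 408 (EV, day 7) and 336 and 333 (shDrosha, day 7). What the scaling is relative to is not given in the sources used here, so a fall of the sum is a fall relative to that unstated reference. The myeloid miRNA miR-223 was the most abundant miRNA in all 8 libraries, with 14% to 27.2% of miRNA reads.

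**Figure D1:**
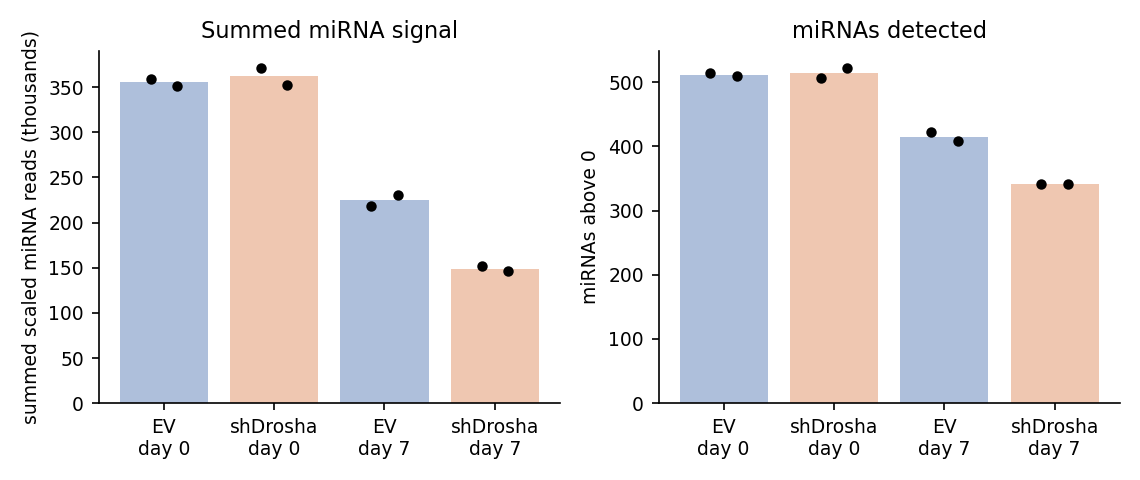
Summed scaled miRNA reads in kilo-reads (left) and number of miRNAs above 0 at full depth (right) in each group. Bars are means and points are the 2 libraries; the sums of day 7 with shDrosha, at 151534 and 146774, lie below those of EV at 218406 and 230672.

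The first comparison asked how miRNAs of control cells changed over the 7 days of myeloid culture. The miRNA of stem cells and endothelium miR-126 fell from among the most abundant miRNAs of day 0, by 5.68 ± 0.16 on the log2 scale (adjusted p = 2.1e-05), and its partner arm miR-126* fell by 5.24 ± 0.09 (adjusted p = 4.5e-06). Most miRNAs of the imprinted cluster at 14q32 and of the proliferation-linked 17-92 cluster and its paralogs fell as well (52 of 61 and 21 of 26; camera adjusted p = 2.9e-08 and 0.00054, and adjusted p = 0.14 and 0.25 with an estimated correlation). In the opposite direction, miR-124, best known from neurons, was at 0 reads in all 4 libraries of day 0 and at 198 and 183 reads in the EV libraries of day 7, at least 95.8-fold higher. miR-122, best known from liver, rose by 3.04 ± 0.24 (adjusted p = 0.0002), from 41.1 ± 14.5 to 333.6 ± 21.3 scaled reads (SD, n = 2).

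Of the 606 miRNAs, 366 changed in EV cells, 115 up and 251 down (limma), around a median change of -0.615 over all tested. Among the largest rises were also miR-218 (6.16 ± 0.38), miR-1246 (3.75 ± 0.26), miR-193a-5p (3.57 ± 0.22), miR-1249 (3.46 ± 0.12), miR-214 (3.28 ± 0.34), miR-1248 (2.95 ± 0.40) and miR-365 (2.66 ± 0.31), and miR-1228, at 0 reads in EV at day 0, was at least 4.40-fold higher. Among the largest falls, miR-335 and miR-195 went to 0 reads, at least 12.9-fold and 12.6-fold lower, and miR-424* was at least 5.90-fold lower. For miR-363, 460 reads at day 0 stood against 3 at day 7, a ratio of 102 with a 95% counting interval from 34.8 to 498. The ratios were 71.3 (19.5 to 593) for miR-551b, 74.7 (13.1 to 2975) for miR-135a and 45.7 (12.4 to 381) for miR-370, each resting on 1 or 2 reads at day 7.

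In the 14q32 cluster, 52 of 61 measured members fell and 1 rose, also when adjusted over the list alone. The median was -3.28, or -2.08 with members at 0 reads set to their bound, and lay -2.67 from the median of all miRNAs. The most abundant members of the list were miR-376c (-5.42 ± 0.17), miR-345 (-1.35 ± 0.12), miR-409-3p (-3.09 ± 0.22) and miR-494 (-3.21 ± 0.31). The gene of miR-345 starts at 100307859 of chromosome 14, apart from those of miR-376c (101039690), miR-409 (101065300) and miR-494 (101029634). It may thus lie outside the imprinted cluster. Of the 17-92 cluster and its paralogs, 21 of 26 fell and 0 rose, 21 and 0 adjusted over the list alone, with a median of -1.16 relative to all miRNAs. miR-17 fell by 1.78 ± 0.13, miR-19b by 2.73 ± 0.14, miR-93 by 1.78 ± 0.47 and miR-92a by 1.11 ± 0.15, the last with its sign turned under quantile normalization (0.12). The call for miR-93 ended under the other 3 scalings (-1.21, -0.84 and -1.12 with equal library medians, quantile normalization and the miRNA read total; adjusted p from 0.063 to 0.17). Of 7 miRNAs of other tissues, 5 rose and 0 fell, with 5 and 1 adjusted over the list alone. They included miR-124* (at least 8.59-fold higher), while miR-1, of muscle, stood at -1.36 ± 0.61 (adjusted p = 0.11). Of the monocyte and inflammatory list, 6 of 16 rose and 1 fell, in both ways of adjusting; miR-155 rose by 0.65 ± 0.11 (adjusted p = 0.0041), and miR-146a stood at 0.26 ± 0.14 (adjusted p = 0.18), with a call under the other 3 scalings.

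camera set these 4 lists apart from all other miRNAs, with adjusted p-values of 2.9e-08 (14q32, down), 0.00054 (17-92, down), 0.0093 (other tissues, up) and 0.025 (monocyte and inflammatory, up). With an estimated correlation the adjusted p-values were 0.14, 0.25, 0.25 and 0.44, so no call held. The monocyte and inflammatory call also ended for miRNAs detected in all 8 libraries (adjusted p = 0.13) and at or above the median mean level (0.092), and the other-tissue call at or above that level (0.077). Without EV replicate 2 of day 7 the monocyte and inflammatory call ended too (adjusted p = 0.13), and those of miR-196b and miR-93 without EV replicate 1 of day 0 (0.099 and 0.10) and without EV replicate 2 of day 7 (0.092 and 0.12). That of miR-93 ended as well without EV replicate 2 of day 0 (0.094) or either shDrosha library of day 0 (0.062 and 0.063).

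Of the lymphoid list 11 of 13 fell and 1 rose, in both ways of adjusting, without a call by camera (adjusted p = 0.054, and adjusted p = 0.25 with an estimated correlation). camera did call it down with equal library medians (adjusted p = 0.019), quantile normalization (0.027), the miRNA read total (0.039), an offset of 10 (0.028), voom (0.019), a replicate block (0.028) and without EV replicate 1 of day 7 (0.041). miR-181a (-1.44 ± 0.12), miR-181b (-1.63 ± 0.09) and miR-181a* (-1.78 ± 0.39) fell and miR-28-3p rose (0.76 ± 0.17). Without EV replicate 2 of day 0 the calls for miR-181a* (adjusted p = 0.063) and miR-28-3p (0.055) ended. That for miR-181a* ended as well without either EV library of day 7 (0.062 and 0.059) and under quantile normalization (0.052) and the miRNA read total (0.062). The 27 stem-cell-associated members split into 7 up and 12 down, with miR-125b at -1.33 ± 0.14. The 7 HOX-cluster members split into 2 up and 3 down, with miR-10a at -2.35 ± 0.23 and miR-196b at -1.24 ± 0.32 (adjusted p = 0.018). That call ended under the other 3 scalings (-0.66, -0.60 and -0.60). Of 42 myeloid members 10 rose and 20 fell, or 10 and 21 adjusted over the list alone; miR-223 itself stood at -0.13 ± 0.16 (adjusted p = 0.56) and at 0.45 with equal library medians, and miR-142-5p fell by 0.90 ± 0.11, with its sign turned under quantile normalization (0.21). The erythroid list had 1 member up, miR-451 (0.90 ± 0.20, adjusted p = 0.0099), and 3 of 5 down. The mesenchymal list and the epithelial list each had 4 up and 3 down of 9, and the 23a/27a/24 clusters 1 up and 4 down of 10. The let-7 family had 2 up and 5 down of 17 (0 and 4 adjusted over the list alone), the Drosha-independent list 3 up and 4 down of 15, and entries that overlap other small RNAs 2 up and 5 down of 10. For these 10 lists the camera adjusted p-values lay between 0.58 and 0.89. The C19MC list had 1 measured member and was not tested.

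The split of rises and falls depended on scaling: 177 rose and 201 fell with equal library medians, 166 and 192 with quantile normalization and 161 and 195 with the miRNA read total. Of the 366 calls, 140 concerned miRNAs with under 20 reads summed over the 4 libraries, as were 290 of the 606 tested.

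The second comparison followed the same culture in shDrosha cells. Here too miR-126 fell, by 6.22 ± 0.16 (adjusted p = 7.7e-06), 51 of 61 members of the 14q32 list and 24 of 26 of the 17-92 list fell (camera adjusted p = 0.00014 and 0.0010, and adjusted p = 0.17 and 0.19 with an estimated correlation), and miR-124, from 0 reads to 168 and 151, was at least 114-fold higher. Of the 15 members of the Drosha-independent list, miRNAs known or thought to mature without Drosha cleavage, 6 rose and 1 fell (camera, up, adjusted p = 0.0013, and adjusted p = 0.17 with an estimated correlation). The erythroid miRNA miR-451 fell by 3.79 ± 0.20 (adjusted p = 4.9e-05), from 42.7 ± 0.4 to 2.18 ± 0.33 scaled reads (SD, n = 2).

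Of the 606 miRNAs, 386 changed in shDrosha cells, 75 up and 311 down (limma), around a median change of -1.09. Among the largest rises, miR-378* went from 0 reads to 126 and 125, at least 89.4-fold higher; miR-877* (4.15 ± 0.51), miR-1246 (4.11 ± 0.26), miR-218 (4.03 ± 0.38), miR-302c* (4.03 ± 0.88), miR-212 (3.46 ± 0.36), miR-31* (3.45 ± 0.55) and miR-122 (3.45 ± 0.24) followed, and miR-193a-5p stood at a ratio of 22.2 (6.87 to 114) on 3 reads at day 0. Among the largest falls was miR-20a of the 17-92 cluster, from 9275 and 9712 reads to 1 and 23 (-9.24 ± 1.04, adjusted p = 0.00064). Members of 14q32 that went to 0 reads were miR-654-3p, miR-495, miR-323-3p, miR-543 and miR-382, at least 45.6-, 43.6-, 34.6-, 25.4- and 18.2-fold lower. miR-181c and miR-151-3p were at least 42.4- and 22.7-fold lower, and miR-551b fell by 6.04 ± 0.31.

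Of the 14q32 list 51 of 61 members fell and 1 rose (53 and 1 adjusted over the list alone), with a median of -1.91 relative to all miRNAs. In it miR-376c, miR-409-3p and miR-494 stood at -5.25 ± 0.17, -5.22 ± 0.22 and -3.57 ± 0.31, and miR-345, whose gene lies apart, at -1.55 ± 0.12. Of the 17-92 list 24 of 26 fell and 0 rose in both ways of adjusting, median -1.27 relative to all. miR-17 fell by 2.29 ± 0.13, miR-19b by 3.26 ± 0.14, miR-93 by 3.46 ± 0.47 and miR-92a by 1.59 ± 0.15, the last with its sign turned under quantile normalization (0.03). With the miRNA read total the calls for miR-92a (-0.31, adjusted p = 0.069) and miR-345 (-0.28, adjusted p = 0.060) ended. Of the other-tissue list 5 of 7 rose and 0 fell in both ways of adjusting, miR-124* (at least 14.5-fold higher) and miR-1 (1.78 ± 0.61, adjusted p = 0.048) among them; the call for miR-1 ended when any one of 7 libraries was left out, for example shDrosha replicate 1 of day 0 (1.32, adjusted p = 0.24). Of the Drosha-independent list 6 of 15 rose and 1 fell, or 5 and 0 adjusted over the list alone. miR-320a rose by 0.38 ± 0.07 (adjusted p = 0.0061), and miR-877 stood at 0.72 ± 0.49 (adjusted p = 0.26; called up under 7 of 21 alternatives), miR-484 at -0.19 ± 0.13 (adjusted p = 0.26) and miR-320b at -0.07 ± 0.27 (adjusted p = 0.92), the last 2 with their signs turned under each of the 3 other scalings.

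camera called the other-tissue list (up, adjusted p = 0.00014), 14q32 (down, 0.00014), 17-92 (down, 0.0010) and the Drosha-independent list (up, 0.0013). With an estimated correlation the adjusted p-values were 0.17, 0.17, 0.19 and 0.17, so no call held. That of 14q32 also ended for miRNAs detected in all 8 libraries (adjusted p = 0.10).

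Of the remaining lists, 17 of 27 stem-cell-associated members fell and 2 rose, 29 of 42 myeloid members fell and 4 rose (30 and 4 adjusted over the list alone), 9 of 13 lymphoid members fell and 0 rose, and 4 of 5 erythroid members fell and 0 rose. Among them miR-125b fell by 2.08 ± 0.14 (-0.19 and no call under quantile normalization, adjusted p = 0.19), miR-10a by 3.84 ± 0.23, miR-181a by 1.89 ± 0.12, miR-142-5p by 2.31 ± 0.11 and miR-144* to 0 reads (at least 5.02-fold lower), and miR-196b rose by 1.58 ± 0.32 (adjusted p = 0.0069). For 4 abundant miRNAs that fell, the sign turned under another scaling: miR-223 (-0.68 ± 0.16, and 0.60 with the miRNA read total), miR-155 (-0.69 ± 0.11, and 0.59), miR-16 (-1.13 ± 0.23, and 0.15) and let-7a (-1.32 ± 0.17, and 0.42 under quantile normalization). miR-146a stood at 0.07 ± 0.14 (adjusted p = 0.73; called up under 3 of 21 alternatives, the other scalings) and miR-21 at -1.69 ± 0.70 (adjusted p = 0.083; called down under 5 of 21, adjusted p from 0.0094 to 0.71). Of the let-7 family 9 of 17 fell and 0 rose (8 and 0 adjusted over the list alone), and of the 23a/27a/24 clusters 8 of 10 fell and 0 rose. For the lists without a call the camera adjusted p-values lay between 0.17 and 0.98. Without shDrosha replicate 1 of day 0 the calls for miR-223 and miR-196b ended (adjusted p = 0.10 and 0.053), without replicate 2 of day 0 that of miR-16 (0.050), and without shDrosha replicate 2 of day 7 those of miR-223 and miR-302c* (0.081 and 0.061).

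Both vectors shared more miRNAs than independent lists would: 39 rose in both (14.2 by chance; Fisher's exact test, two-sided, p = 3.0e-12) and 178 fell in both (128.8 by chance; p = 3.3e-16), while 35 moved in opposite directions. By chance 90.1 would have moved in opposite directions. The libraries compared differ, but the fit pooled the spread of each miRNA over all libraries. The calls in both vectors are therefore not independent, and these p-values may be too small. Under other scalings the shDrosha split was 166 up and 199 down (equal library medians), 160 and 182 (quantile) and 138 and 225 (miRNA read total).

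**Figure D2:**
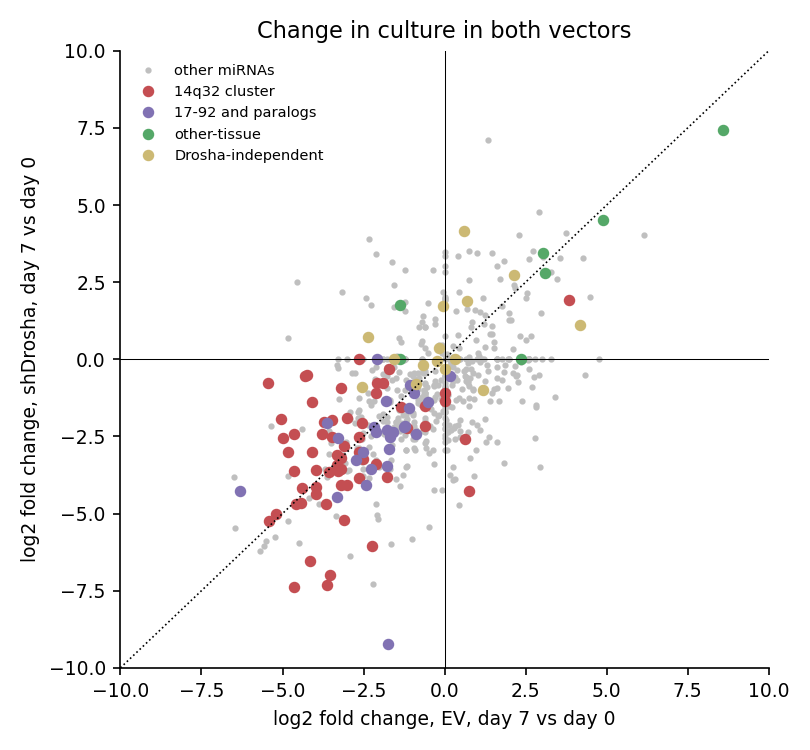
Log2 fold change from day 0 to day 7 in EV (x axis) and in shDrosha cells (y axis) for the 606 tested miRNAs, with members of 4 lists coloured and the dotted line marking equal change. Members of 14q32 lie mostly in the lower left quadrant, and miR-124 lies at the upper right at 8.60 and 7.44.

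The third comparison set shDrosha against EV cells at day 0. The knockdown libraries differed little in sum, and camera set no list apart from the other miRNAs. A few miRNAs differed strongly: miR-378* was at 0 reads in both shDrosha libraries against 46 and 55 in EV, at least 44.3-fold lower, although the shDrosha libraries were deeper. The erythroid miRNA miR-451 was higher, by 1.47 ± 0.20 (adjusted p = 0.0052), and the HOX-cluster miRNA miR-196b was lower, by -1.94 ± 0.32 (adjusted p = 0.0093). The call for miR-196b ended with only the 4 libraries compared (limma adjusted p = 0.0502). It also ended without replicate 1 of EV (-1.68) or of shDrosha (-1.79) at day 0.

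In all, 154 miRNAs changed, 61 up and 93 down (limma), around a median of -0.01. Higher in shDrosha cells were miR-1248 (1.70 ± 0.40), miR-628-5p (1.69 ± 0.36), miR-214 (1.33 ± 0.34), miR-3614-5p (1.06 ± 0.22), miR-454* (0.99 ± 0.24), miR-342-3p (0.75 ± 0.12) and miR-29b-1* (0.74 ± 0.14), and miR-193b at a ratio of 5.56 (1.42 to 47.8) on 2 reads in EV. miR-1228 was at 0 reads in EV and at 8 and 7 in the deeper shDrosha libraries. Their mean of 3.48 ± 0.87 scaled reads (SD, n = 2) lay under the EV floor of 4.06, so no fold is given. Its call ended with an offset of 10 (adjusted p = 0.17). Lower were miR-1254 (-4.13 ± 0.51), miR-1307 (-2.65 ± 0.56), miR-486-3p (-2.56 ± 0.39), let-7i (-2.45 ± 0.38), miR-212 (-2.17 ± 0.36) and miR-500a (-1.94 ± 0.42). miR-324-3p stood at 49 reads in each EV library and at 0 and 1 in shDrosha, a ratio of 291 (51.0 to 11605), and miR-193a-5p at a ratio of 8.90 (2.22 to 51.1) on 3 reads. miR-146a fell by 0.74 ± 0.14 (adjusted p = 0.015).

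Among 15 Drosha-independent members 3 were called up, miR-1228 at 0 reads in EV among them, and 2 down, in both ways of adjusting. miR-320a rose by 0.29 ± 0.07 (adjusted p = 0.043) and miR-484 by 0.53 ± 0.13 (adjusted p = 0.037). Both calls ended with a replicate block (adjusted p = 0.081 and 0.060), without a filter (0.17 and 0.075) and with eBayes without trend (0.14 and 0.066), and that of miR-320a also under quantile normalization (0.21) and the miRNA read total (0.065). miR-877 stood at 0.46 ± 0.49 (adjusted p = 0.56) and miR-320b at 0.64 ± 0.27 (adjusted p = 0.16). Of 61 members of 14q32, 7 rose and 10 fell, of 26 members of the 17-92 list 0 rose and 3 fell (0 and 1 adjusted over the list alone). Of 42 myeloid members 7 rose and 5 fell, and of 17 let-7 members 0 rose and 2 fell. No list was called by camera (adjusted p from 0.90 to 0.97); fry, which asks only whether a list moves on balance, called the erythroid list up (adjusted p = 0.038) and the epithelial list down (adjusted p = 0.036). Several miRNAs known from stem and myeloid cells passed no threshold: miR-126 (-0.18 ± 0.16), miR-10a (-0.07 ± 0.23) and let-7a (-0.06 ± 0.17), each with a sign that turned with equal library medians, and miR-223 (0.24 ± 0.16), miR-125b (0.31 ± 0.14), miR-155 (0.10 ± 0.11), miR-181a (0.42 ± 0.12; called up under 5 of 21 alternatives), miR-142-5p (0.27 ± 0.11), miR-21 (-0.55 ± 0.70), miR-16 (0.39 ± 0.23) and miR-144* (1.14 ± 0.63).

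When libraries were left out, this comparison was the least stable, while scaling ended or turned 1 of its 23 named calls, against 11 of 39 for the knockdown at day 7. Of the 23 named miRNAs past the threshold, 18 lost it when 1 of the 8 libraries was left out; without shDrosha replicate 1 of day 0 the count was 102 in place of 154, miR-320a stood at an adjusted p of 0.11 and miR-484 at 0.17. With equal library medians 99 rose and 70 fell, and with quantile normalization 76 and 73. Of the 154 calls, 83 concerned miRNAs with under 20 reads summed over the 4 libraries, as were 217 of the 606 tested.

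The fourth comparison set shDrosha against EV cells at day 7. Most changed miRNAs were lower with the knockdown, among them let-7a (-1.73 ± 0.17, adjusted p = 0.00071), miR-155 (-1.24 ± 0.11, adjusted p = 0.00052), miR-142-5p (-1.14 ± 0.11, adjusted p = 0.00054), miR-10a (-1.57 ± 0.23, adjusted p = 0.0027) and miR-451 (-3.21 ± 0.20, adjusted p = 0.0002). Under quantile normalization the calls for miR-155 (-0.22, adjusted p = 0.087) and miR-142-5p (-0.22, adjusted p = 0.082) ended. Against this fall, 3 members of the Drosha-independent list were higher: miR-320a by 0.85 ± 0.07 (adjusted p = 0.00048), miR-484 by 1.02 ± 0.13 (adjusted p = 0.0017), and the mirtron miR-877, an intron of ABCF1 cut out by splicing, by 3.54 ± 0.49 (adjusted p = 0.0024). In scaled reads, miR-320a stood at 2967 ± 102 (SD, n = 2) in EV and 5336 ± 366 (SD, n = 2) in shDrosha, miR-484 at 1849 ± 181 and 3739 ± 384, and miR-877 at 10.3 ± 8.0 and 112.8 ± 3.4.

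**Figure D3:**
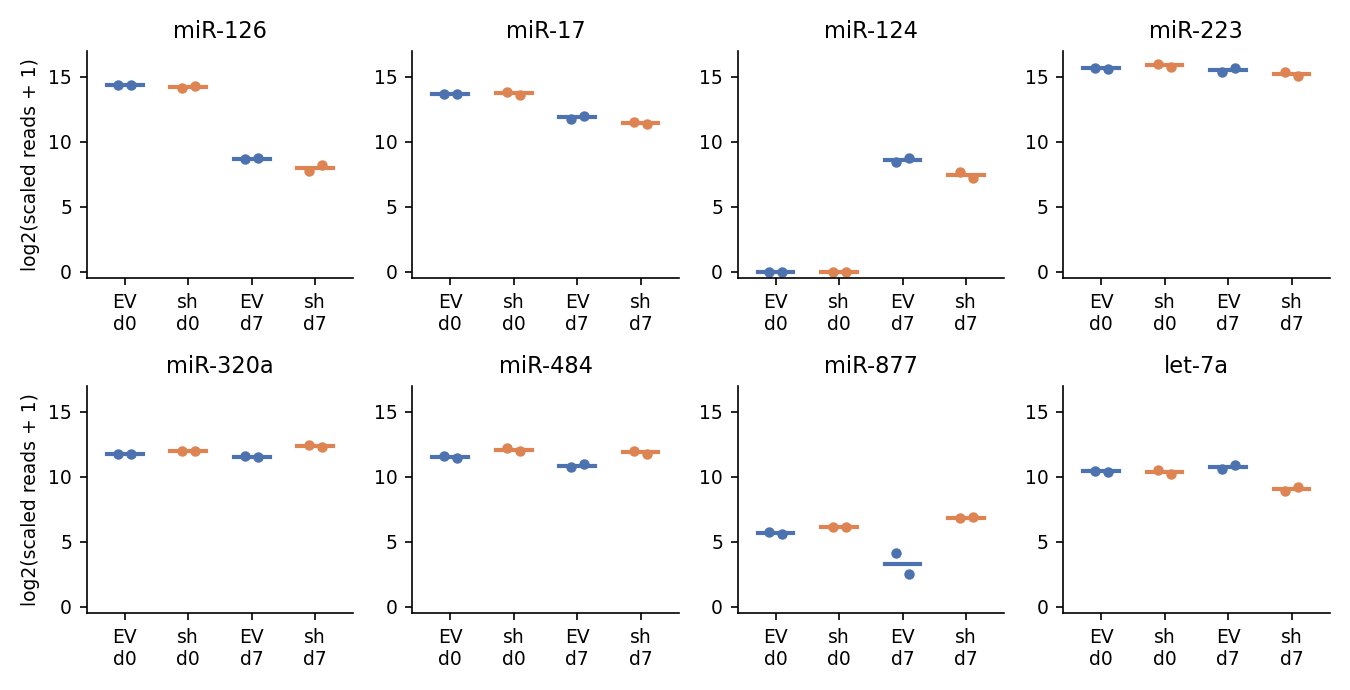
Log2(scaled reads + 1) of 8 miRNAs in the 4 groups (EV, empty vector; sh, shDrosha; d0 and d7, days 0 and 7); points are the 2 libraries and lines are group means. miR-320a, miR-484 and miR-877 are higher with shDrosha at day 7 while let-7a is lower; miR-223 differs by -0.31 there, a sign that turns with equal library medians (0.33).

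Of the 606 miRNAs, 273 changed, 61 up and 212 down (limma), around a median of -0.30. Higher in shDrosha cells, besides miR-877, were miR-877* (3.19 ± 0.51) and miR-424* (2.92 ± 0.42), and, against 0 reads in EV, miR-101* (at least 3.19-fold), miR-450b-5p (at least 1.31-fold) and miR-486-3p (at least 1.05-fold). On 1 or 2 reads in EV, miR-370 stood at a ratio of 9.37 (2.41 to 80.4), miR-539 at 14.5 (2.38 to 592), miR-26b* at 13.9 (2.29 to 571) and miR-379 at 12.3 (2.0 to 507). The largest fall was that of miR-20a, from 593 and 562 reads to 1 and 23 (-7.36 ± 1.04, adjusted p = 0.0024). miR-32* was at least 13.0-fold lower, miR-181c 11.3-fold, miR-500a 8.61-fold, miR-1248 7.04-fold, miR-551a 5.59-fold, miR-382 5.41-fold, miR-33a 5.08-fold and miR-495 5.02-fold, all at least that much against 0 reads in both shDrosha libraries. miR-340 stood at a ratio of 70.0 (18.7 to 589) on 2 reads.

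In the Drosha-independent list 6 of 15 members rose and 2 fell, or 7 and 2 adjusted over the list alone. Besides miR-320a, miR-484, miR-877 and miR-877*, the mirtrons miR-1226 (1.47 ± 0.38, adjusted p = 0.025) and miR-1227 (1.70 ± 0.30, adjusted p = 0.0060) rose. miR-320c (-2.10 ± 0.32) and miR-1234 (-2.20 ± 0.31) fell; miR-320c has a sequence close to that of miR-320a and miR-320b, so reads could move between them. miR-320b stood at 0.82 ± 0.27 (adjusted p = 0.059) and was called up under 7 of 21 alternatives (adjusted p from 0.0043 to 0.24). The list's median lay 0.91 above that of all miRNAs and camera called it (up, adjusted p = 0.013; adjusted p = 0.63 with an estimated correlation). The call ended with equal library medians (adjusted p = 0.068) and quantile normalization (adjusted p = 0.15), although the list still lay 0.91 and 0.95 above all miRNAs, and without the miR-320 family (adjusted p = 0.064).

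**Figure D4:**
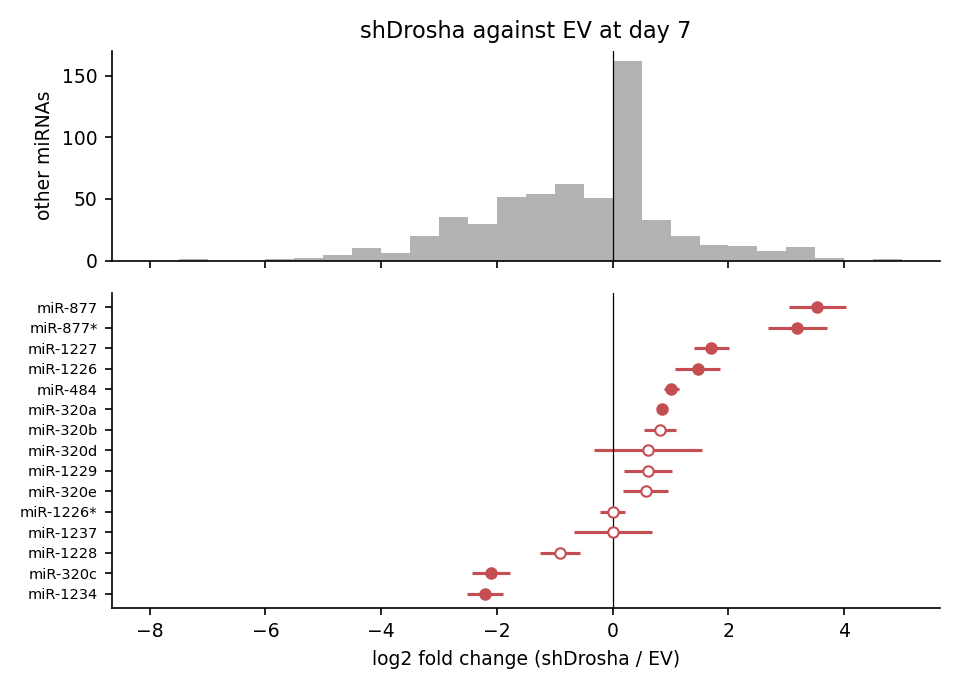
Log2 fold change of shDrosha against EV at day 7 for the 591 tested miRNAs outside the Drosha-independent list (top, number of miRNAs per bin) and for its 15 members (bottom, point and standard error, filled when past the threshold). Of the list 6 members rose and 2 fell, and 134 of the 606 miRNAs were at 0 reads in all 4 libraries, which places them at 0.

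Of the other lists, 10 of 17 let-7 members fell and 2 rose, in both ways of adjusting; let-7f (-0.96 ± 0.15), let-7g (-1.09 ± 0.12) and let-7d (-1.21 ± 0.24) fell next to let-7a. The call for let-7f ended with equal library medians (-0.32, adjusted p = 0.073), and that for let-7d under quantile normalization (-0.22, adjusted p = 0.26) and the miRNA read total (-0.63, adjusted p = 0.057). Of the 23a/27a/24 clusters 8 of 10 fell and 0 rose (9 and 0 adjusted over the list alone): miR-23a by 1.05 ± 0.14, miR-24 by 0.69 ± 0.12, miR-27a by 0.95 ± 0.13 and miR-23b by 0.81 ± 0.17, the last with its sign turned under quantile normalization (0.01). Under other scalings the calls ended for miR-24 (-0.06 with equal library medians, -0.11 with the miRNA read total), miR-27a (-0.32 with equal library medians, -0.03 with quantile normalization) and miR-23b (all 3). Of the monocyte and inflammatory list 9 of 16 fell and 0 rose (11 and 0 adjusted over the list alone); miR-146a fell by 0.93 ± 0.14 (-0.29 and -0.34 and no call with equal library medians and the miRNA read total, adjusted p = 0.066 and 0.052) and miR-146b-5p by 1.91 ± 0.23, and miR-21 stood at -2.19 ± 0.70 (adjusted p = 0.052). For miR-21, 8 of 21 alternatives gave a call down (adjusted p from 0.0077 to 0.23). Of 42 myeloid members 20 fell and 4 rose (22 and 4 adjusted over the list alone), of 27 stem-cell-associated members 11 fell and 1 rose, of 26 members of the 17-92 list 14 fell and 2 rose (15 and 3), and of 61 members of 14q32 8 fell and 6 rose (6 and 6). The erythroid list had 3 down and 1 up of 5, with miR-144* at least 2.41-fold lower. The other-tissue list had 0 up and 2 down of 7, and the mesenchymal list 0 up and 5 down of 9. None of these lists was called by camera (adjusted p from 0.081 to 0.94), except the monocyte and inflammatory list without EV replicate 1 of day 7 (down, adjusted p = 0.041; adjusted p = 0.63 with an estimated correlation and all libraries). miR-125b (-0.44 ± 0.14, adjusted p = 0.047) and miR-126 (-0.72 ± 0.16, adjusted p = 0.014) fell with the deposited scaling and turned sign under quantile normalization (0.62 and 0.19). The calls for both ended without EV replicate 2 of day 7 (adjusted p = 0.17 and 0.082) and without EV replicate 1 of day 7 (0.083 and 0.056), and that for miR-125b without either shDrosha library of day 7 (0.12 and 0.17) or EV library of day 0 (0.085 each). Without EV replicate 2 of day 7 the call for miR-23b ended too (0.063). Those for miR-370, miR-539, miR-379 and miR-144* ended without shDrosha replicate 1 of day 7 (0.074, 0.065, 0.053 and 0.061) and those for miR-370, miR-144* and let-7d without replicate 2 (0.080, 0.060 and 0.063). miR-223 (-0.31 ± 0.16), miR-16 (-0.52 ± 0.23) and miR-181a (-0.03 ± 0.12) passed no threshold and turned sign with equal library medians, and miR-196b stood at 0.87 ± 0.32 (adjusted p = 0.076), with a call up under the other 3 scalings.

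The split moved with scaling to 131 up and 156 down (equal library medians), 146 and 151 (quantile) and 101 and 171 (miRNA read total). Of the 273 calls 108 concerned miRNAs with under 20 reads summed over the 4 libraries, as were 328 of the 606 tested. Groups did not overlap for 361 of the 606 miRNAs (59.6%), against 33.3% by chance for independent libraries without ties. For the knockdown at day 0 it was 375 (61.9%). These shares cannot be compared directly, since miRNAs at 0 reads in all 4 libraries cannot separate. There were 134 of them at day 7 and 30 at day 0. Among miRNAs with a read the share was thus higher at day 7. Ties at 0 also make the chance value too high.

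The fifth comparison tested whether the knockdown effect differed between the days. It did for 282 miRNAs, with a more positive effect at day 7 for 86 and a more negative one for 196 (limma interaction). miR-20a had the largest negative difference (-7.49 ± 1.47, adjusted p = 0.0096), and miR-324-3p the largest positive one (7.05 ± 1.42, adjusted p = 0.011), since it was nearly absent with shDrosha at day 0. Both calls ended without shDrosha replicate 1 of day 0 (adjusted p = 0.055 and 0.058). The other named positive differences were those of miR-378* (5.77 ± 0.25), miR-486-3p (5.55 ± 0.55), miR-101* (5.36 ± 0.43) and miR-1254 (4.79 ± 0.72), and the negative ones those of miR-1248 (-6.42 ± 0.57), miR-641 (-5.17 ± 0.56), miR-181c (-5.05 ± 0.25) and miR-33a (-4.94 ± 0.50). Of these 8, all except miR-1254 had a group at 0 reads, so the fitted values depend on the offset and are no bounds. With an offset of 10 they were 2.64 (miR-378*), 2.22 (miR-486-3p), 2.04 (miR-101*), 2.17 (miR-1254), -2.50 (miR-1248), -2.11 (miR-641), -2.03 (miR-181c) and -2.02 (miR-33a), and 3.18 for miR-324-3p. No list was called by camera (adjusted p from 0.14 to 0.71), although the Drosha-independent list was called up for miRNAs detected in all 8 libraries (adjusted p = 0.0027) or with at least 10 reads (0.016). With an estimated correlation and all miRNAs it had an adjusted p of 0.75. The calls of both days overlapped no more than independent lists would: 6 miRNAs rose on both (6.14 by chance; Fisher's exact test, two-sided, p = 1), 34 fell on both (32.5 by chance; p = 0.72) and 19 moved in opposite directions. For opposite directions the number by chance was 30.7. Here too the calls share 1 estimate of the spread of each miRNA and are not independent. Under other scalings the split was 118 and 153 (equal library medians), 130 and 126 (quantile) and 125 and 147 (miRNA read total).

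The mean difference between shDrosha and EV over both days was called for 302 miRNAs, 79 up and 223 down (limma). Such a mean can rest on 1 day. For example, miR-378* was at least 44.3-fold lower at day 0 and stood at -0.335 at day 7. The effects on miR-20a, miR-101* and miR-181c also differed between days (interaction -7.49, 5.36 and -5.05). The highest mean rises were those of miR-877 (2.0 ± 0.35, adjusted p = 0.0065), miR-101* (1.83 ± 0.21), miR-450b-5p (1.77 ± 0.32), miR-26b* (1.53 ± 0.40) and miR-769-3p (1.48 ± 0.31). The deepest mean falls were those of miR-32* (-3.61 ± 0.15), miR-20a (-3.61 ± 0.73, adjusted p = 0.010), miR-500a (-3.45 ± 0.30), miR-378* (-3.22 ± 0.13) and miR-181c (-2.86 ± 0.13). All of these except miR-877, miR-26b*, miR-769-3p and miR-20a had a group at 0 reads, so their fitted means depend on the offset. With an offset of 10 they were 0.66 (miR-101*), 0.50 (miR-450b-5p), -1.90 (miR-32*), -1.35 (miR-500a), -1.64 (miR-378*) and -1.33 (miR-181c), and 0.56 and 0.68 for the low miR-26b* and miR-769-3p. Of the Drosha-independent list 7 of 15 rose and 3 fell, in both ways of adjusting, and camera gave an adjusted p of 0.059 (adjusted p = 0.78 with an estimated correlation). It called the list up for miRNAs detected in all 8 libraries (adjusted p = 0.00015), at or above the median mean level (0.0002) or with at least 10 reads (0.0016), and with voom (0.0034), a replicate block (0.041) and an offset of 10 (0.043). Under other scalings the split was 158 and 121 (equal library medians), 149 and 143 (quantile) and 117 and 188 (miRNA read total), so the surplus of falls turned under 2 of them. The calls for miR-20a, miR-26b* and miR-769-3p ended without shDrosha replicate 1 of day 0 (adjusted p = 0.051, 0.089 and 0.054). That for miR-20a also ended without shDrosha replicate 2 of day 0 (0.056), and that for miR-26b* without any library except those of EV at day 7 (0.072 to 0.089).

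In the GENCODE v29 annotation of the GRCh38 assembly, the gene of miR-126 lies on chromosome 9 from 136670602 to 136670686 in an intron of EGFL7, and that of miR-223 on chromosome X from 66018870 to 66018979 in an exon of a non-coding transcript. The genes of miR-17 (91350605 to 91350688) and miR-20a (91351065 to 91351135) lie on chromosome 13 in the transcript MIR17HG. miR-320a comes from chromosome 8, 22244962 to 22245043, outside any gene on its strand. miR-484 comes from chromosome 16, 15643294 to 15643372, in an exon of NDE1, and miR-877 from chromosome 6, 30584332 to 30584417, in an intron of ABCF1. Of the 14q32 cluster, miR-370 starts at 100911139 and miR-409 at 101065300 of chromosome 14. The authors' build was hg19, per the submitters' processing notes; the table holds names without coordinates, so no position was carried between builds.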

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

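All tests of explanations in this part were chosen after the result was seen, except the count of other splits of the libraries, which was planned.

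The knockdown effect differed between day 0 and day 7, by the limma interaction test, for 282 miRNAs. Those named by the rule of the largest difference were miR-324-3p (7.05), miR-378* (5.77), miR-486-3p (5.55), miR-101* (5.36) and miR-1254 (4.79) toward day 7, and miR-20a (-7.49), miR-1248 (-6.42), miR-641 (-5.17), miR-181c (-5.05) and miR-33a (-4.94) away from it. All except miR-324-3p, miR-1254 and miR-20a had a group at 0 reads, so their values depend on the offset; with an offset of 10 miR-101* stood at 2.04, miR-1248 at -2.50 and miR-181c at -2.03. No other group comparison in the design had a test of this kind, and groups of 2 libraries allow no test for a library far from the others. For the mean knockdown effect over both days, 1 of the 18 splits that keep 2 libraries of each day on each side called as many miRNAs, the real one with 302; the highest of the others called 282, and it exchanged the vectors at 1 day and so is the interaction itself. The next highest called 138, and 18 splits are too few for a share under 0.05.

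Members of the Drosha-independent list were higher with shDrosha than with EV at day 7, while most changed miRNAs were lower. This is a difference between vectors at that day. Within shDrosha cells from day 0 to day 7, miR-320a rose (0.38 ± 0.07), while miR-877 (0.72 ± 0.49) and miR-484 (-0.19 ± 0.13) passed no threshold. Reads shared within the miR-320 family did not account for all of the rises, since 5 of the 6 members that rose lay outside it. Among these, miR-877 and miR-877* are arms of 1 precursor. The list did not come closer to the other miRNAs under other scalings: its median lay 0.91 above that of all miRNAs with the deposited scaling (0.79 to 1.04 over the 4 pairs of libraries), 0.91 with equal library medians (0.79 to 1.04), 0.95 with quantile normalization (0.71 to 1.04) and 1.19 with the miRNA read total (1.17 to 1.56). Equal medians shift all miRNAs of a library alike and so could not have changed this. The miRNA read total multiplies each library by 1 factor, so it could act only through the offset and miRNAs at 0 reads. With it the median of all miRNAs lay at 0. camera still called the list under 1 of the 3 (adjusted p = 0.036 with the miRNA read total). With equal medians the camera adjusted p was 0.068 with and 0.028 without the 134 miRNAs at 0 reads in all 4 libraries of day 7. With quantile normalization it was 0.15 with them and 0.14 without. Dropping them lowered it under the deposited scaling too (0.013 to 0.0057), so why calls ended was not settled. Quantile normalization alone was free to change the distance of the list from all miRNAs, and the distance did not shrink under it. That argues against scaling as the source of the distance, on 1 alternative only. Whether camera calls the list does depend on the scaling. The share that rose in the list and outside it was 40% and 9.31% with the deposited scaling, 53.3% and 20.8% with equal library medians, 53.3% and 23.4% with quantile normalization and 46.7% and 15.9% with the miRNA read total. Processing that bypasses Drosha is a candidate explanation that stays open, since Drosha was not measured. The adjusted p of 0.63 from camera with an estimated correlation (0.035 for this list) decides nothing, since that setting rests on 4 residual degrees of freedom.

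Single miRNAs were nearly absent from both libraries of 1 group while above 30 scaled reads in the other 3: miR-378* with shDrosha at day 0, and miR-181c, miR-20a, miR-340 and miR-34a* with shDrosha at day 7. miR-324-3p, nearly absent with shDrosha at day 0, is not in this set, since its means at day 7 were 3.58 and 6.20 scaled reads. For miR-378*, miR-181c, miR-340 and miR-34a* the partner arm changed by -0.265, 2.495, 0.135 and -0.26, so loss of the whole precursor was not seen. For miR-20a the cluster mates, cut from other hairpins of the transcript, changed by a median of -0.525. That cannot show whether the precursor of miR-20a itself was lost. For miR-20a, reads counted to miR-17, miR-20b or miR-106a covered 38.3 ± 18.3% of its loss (SE, n = 2 per group) with equal library medians, the highest of the 4 scalings, and -109% with the deposited one, so a share of the loss could lie there and this stays open. Another difference in how reads of single mature miRNAs were assigned could remain, as could a biological one; neither was tested.

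miR-124 appeared at day 7 in both vectors, with 700 reads in the 4 libraries of day 7 and 0 among 2121707 miRNA reads of day 0. Too few reads at day 0 was not the reason, since the day 7 level predicted at least 287 reads in each library of day 0. Neural material would likely bring miR-9; its main arm was at 0 reads at day 7 and its other arm miR-9* at 4, in 1 EV library, together 0.571 per 100 reads of miR-124, but how much it would bring is not known from these data, so this stays open. Myeloid culture is a candidate explanation, since miR-124 rose in 2 of 2 vectors, but time and medium changed together and cannot be told apart.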

How the results depend on the processing

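Scaling to the miRNA read total, the filter of at least 10 reads, voom and the list without the miR-320 family were chosen after the data were seen. Of 163 named results past the threshold, 105 kept direction and threshold under every alternative run. Causes were not tested unless stated.

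Fewer miRNAs entered some settings, which by construction changes counts. Detected in all 8 libraries, the counts were 174 and 194 (day 7 against day 0, EV and shDrosha), 36 and 167 (knockdown at days 0 and 7), 126 (interaction) and 133 (both days). At or above the median mean level they were 212, 237, 46, 199, 162 and 167. With at least 10 reads they were 55 (knockdown at day 0), 181 (interaction) and 182 (both days). For the knockdown at day 0 the count was 90 without a filter and 91 with only its 4 libraries. With only the 4 libraries of a contrast, 3 of 39 named calls ended in EV and 4 of 42 in shDrosha. For the knockdown, 13 of 23 ended at day 0 and 9 of 39 at day 7. Those of day 7 included miR-877* (adjusted p = 0.054), let-7d (0.081), miR-26b* (0.088) and miR-126 (0.097). Leaving out 1 library gave 324 to 357 (EV), 321 to 395 (shDrosha), 102 to 151 (knockdown at day 0, lowest without shDrosha replicate 1 of day 0), 223 to 272 (day 7), 228 to 293 (interaction) and 248 to 308 (both days); the lone library left was assumed to vary like the other groups. With an offset of 10 the calls ended for miR-1228, miR-193b, miR-214, miR-212, miR-500a and miR-320a at day 0 (adjusted p from 0.052 to 0.17) and for miR-424* (0.086) and miR-144* (0.070) at day 7. voom gave 363, 463, 222, 325, 315 and 327, with 345, 375, 139, 265, 251 and 264 shared in the same direction.

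Signs turned with scaling for these named miRNAs that passed the threshold before or after the change. In EV from day 0 to day 7 these were miR-223 (0.45 equal medians, 0.54 read total), miR-320a (0.39, 0.66 quantile, 0.48 read total), and under quantile normalization miR-142-5p (0.21), miR-484 (0.46) and miR-92a (0.12). In shDrosha they were, in the order equal medians, quantile and read total, miR-223 (0.28, 0, 0.60), miR-155 (0.27, 1.21, 0.59), miR-484 (0.77, 1.23, 1.09) and miR-320b (0.89, 1.02, 1.19), with let-7a (0.42) and miR-92a (0.033) under quantile only and miR-16 (0.15) under the read total only. For the knockdown at day 7 they were miR-125b (0.20, 0.62, 0.15) and miR-181a (0.61, 0.46, 0.56), with miR-126 (0.19) and miR-23b (0.013) under quantile only. Signs also turned, with no call under either scaling, for miR-21 (0.53), miR-144* (0.50) and miR-16 (0.35) in EV, for miR-126 (0.068), miR-10a (0.17) and let-7a (0.19) for the knockdown at day 0, and for miR-223 (0.33) and miR-16 (0.12) at day 7, all with equal medians.

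fry, which does not compare a list with other miRNAs, called 13 results for lists in the direction opposite to camera and 40 in the direction of camera that camera had not called, at an adjusted p under 0.05. The medians of the 13 were: 23a/27a/24 in EV (-0.045); monocyte and inflammatory (-0.43), mesenchymal (-1.21) and overlapping small RNAs (-0.91) in shDrosha; stem-cell-associated (-0.26), HOX-cluster (0), lymphoid (0.02), other-tissue (-0.36) and 14q32 (0) for the knockdown at day 7; lymphoid (0.80) for the interaction; stem-cell-associated (-0.11), lymphoid (-0.083) and 14q32 (-0.058) for both days. Where most miRNAs fall, a list that falls less can be called up by camera and down by fry.

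With the replicate number as a block, the counts were 351, 378, 119, 273, 274 and 289. The pairing had little support: deviations of equal replicate numbers correlated between groups at 0.067, -0.003, 0.046, -0.008, 0.19 and -0.12. With the block camera also called the lymphoid list in EV (adjusted p = 0.028) and the Drosha-independent list over both days (0.041), while the calls ended for miR-320a (0.081), miR-484 (0.060), miR-214 (0.074) and miR-454* (0.065) in the knockdown at day 0, miR-125b in that at day 7 (0.065) and miR-1 in shDrosha (0.063).

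Depth limits low miRNAs: on simulated data 41.9% of 2-fold changes were recovered over all miRNAs and 79.0% at 40 reads or more, and 21.5% of calls below 40 reads were unchanged miRNAs.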

Other observations

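The miRNAs in the next 2 paragraphs were chosen after their values were seen, and the test on the 17-92 cluster was chosen after its result was seen; the test on minor arms was planned.

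Several miRNAs outside the lists' examples changed strongly in culture (limma, Benjamini-Hochberg). The hypoxia-responsive miR-210 fell from 1964 ± 38.5 to 90.4 ± 36.2 scaled reads (SD, n = 2) in EV (-4.49 ± 0.39, adjusted p = 0.00027) and from 2918 ± 172 to 48.0 ± 21.8 (SD, n = 2) in shDrosha (-5.97 ± 0.39, adjusted p = 8.0e-05). miR-130a, known from progenitors and megakaryocytes, fell by 4.82 ± 0.35 and 3.78 ± 0.35. The HOX-cluster miRNAs parted: miR-10b rose by 2.60 ± 0.30 in EV and 3.25 ± 0.30 in shDrosha while miR-10a fell in both. Of the neighbours miR-221 and miR-222, which target KIT, miR-221 fell by 3.27 ± 0.54 in EV and stood at -1.28 ± 0.54 in shDrosha (adjusted p = 0.084), with no call under any of the 3 other scalings. miR-222 stood at -0.54 ± 0.07 and -0.89 ± 0.07 with the deposited scaling, and its sign turned with equal library medians (0.04 and 0.08), quantile normalization (0.13 and 0.85) and the miRNA read total (0.13 and 0.39), so no direction is given. miR-147b, known from activated macrophages, was at 12 and 14 reads in EV at day 7 and at 0 in the other 6 libraries.

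Under the knockdown, miR-7, miR-374b and miR-30c were lower at both days: by -1.35 ± 0.19 and -2.30 ± 0.19, -1.47 ± 0.18 and -3.22 ± 0.18, and -0.76 ± 0.12 and -2.44 ± 0.12 at days 0 and 7, with adjusted p-values from 0.0001 to 0.0079, and were called lower at both days under the 3 other scalings as well.

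A hypothesis was that minor arms, which turn over faster, fell more than major arms under the knockdown at day 7. It was not supported: over 50 precursors with at least 20 reads of each arm in EV at day 7, the median difference of minor from major arms was 0.22 (sign permutation, two-sided, p = 0.33), with 22 lower and 28 higher. Arms were ranked by mean level over all 8 libraries, the tested ones included. An arm could thus rank as minor because it fell. Another was that members of the 17-92 cluster, cut from 1 primary transcript, moved alike. The SD over the 6 main arms was 2.78, but 0.379 without miR-20a, whose mates ran from -1.23 to -0.21. The loss of miR-20a had prompted the test, so the hypothesis stays open.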
